A study of Mus musculus with 24 samples.

How the data were processed

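RNA sequencing of polyadenylated RNA from mouse mammosphere cultures was analysed from the authors' processed tables. Libraries were made with the TruSeq RNA kit, per the labels' protocols. Per the submitters' processing notes the tools used upstream were CASAVA 1.9, TopHat2 2.0.8, Bowtie2 2.1.0, SAMtools 0.1.18 and HTSeq 0.5.3p9, with the mouse build mm10, and the authors' statistics came from DESeq2 1.10.1. There were 6 deposited tables, 1 per comparison, covering 24 samples in 8 groups. Replicates are biological replicates, per the file headers.

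The authors' tables give for each gene a signal, the mean normalised read count of each group over its libraries, and the mean over both groups, per the file headers. The authors' log2 fold changes come from their DESeq2 contrast, except that the Nutlin-3 table gives the mean of the log2 fold changes of treated and untreated samples paired by tumour, per the file headers. The deposited p-values are those of the authors' test, and the deposited adjusted p-values equal the Benjamini-Hochberg adjustment over the listed genes, which was checked by recomputing it. Per the file headers the tables list only genes whose mean over the comparison was above 10. They listed 13873 genes for Myc-ER, 13288 for ErbB2, 13038 for Nutlin-3, 14699 for the Trp53 knockout, 13959 for PKH-high and 14382 for Myc-ER in PKH-negative cells. Between 93.9% and 95.5% of the symbols matched GENCODE release M21 on GRCm38, the assembly also called mm10, from which coordinates were taken.

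Only group means are in these tables, so values per sample, their spread and their library totals were not analysed here. The plan fixed before the data were examined set out for this case that a gene is called changed at the authors' deposited adjusted p below 0.05, with no further test on samples. The tables headed with wild-type mammospheres were matched to the empty-vector group, which is the only unsorted wild-type group in the labels. Across the tables that share the empty-vector group, the ratio of its means was nearly constant over genes (1st to 99th percentile spanning 0.00069 to 0.024 on the log2 scale). The Nutlin-3 table used 3 of the 5 untreated tumour libraries, per the file headers. The table of the knockout has 3 entries that name no gene (reads not uniquely aligned, in no feature, or ambiguous); they hold 28.2% of the knockout's and 29.7% of the control's summed means and were left out. In that table the adjusted p-values were still the authors', which include those entries. The symbol Sept5 occurs in 2 entries of the ErbB2 table and was left out of comparisons between tables.

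The authors' log2 fold changes outside the Nutlin-3 table are nearly all smaller in size than the log2 ratio of the group means. This was counted only over genes whose ratio of means was not small. The gap is large for some genes with high means, such as Esr1 and Dlk1. Which value is nearer the true change cannot be told without values per library. The standard error printed after ± is the authors' log2 fold change divided by the normal quantile of their p-value. It was not computed for Nutlin-3, because there the deposited fold change is not the tested coefficient. Among genes of that table whose ratio of means was not small, 35 have a fold change of the opposite sign to that ratio. Genes with smaller ratios were not counted, so more may differ in sign. Tables were normalised separately by the authors, and levels are compared only within a table unless stated. Reads of near-identical gene copies and of genes overlapping on opposite strands may not be told apart in these counts, since the strand setting of the counting is not given in the sources used here.

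The text names genes by a rule fixed before the data were examined. In each comparison these are Myc, Trp53, Erbb2, Cdkn1a and Mdm2 whatever their result; the 6 largest increases and the 6 largest decreases among changed genes with a mean at or above the median of the changed genes, leaving out gene models without a standard symbol; and, from each list with at least 3 changed members, up to 3 changed members with the largest fold change. Not all genes that the rule allows are printed.

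A set of 33 gene lists of 7 to 42 genes was fixed at the same time. They cover mitosis and G2/M, DNA replication and S phase, ribosome biogenesis, Myc-target metabolic and nucleotide enzymes, p53 targets, CDK inhibitors, the BCL2 family, basal and myoepithelial, luminal, milk protein, mammary stem cell associated and squamous differentiation genes, basement membrane and hemidesmosome, EMT, markers of fibroblasts, macrophages and myeloid cells, lymphocytes, endothelium, adipocytes and erythroid cells, interferon response, NF-kB and inflammatory genes, immediate early and dissociation stress, integrated stress and unfolded protein response, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, lysosome, ErbB ligands and MAPK feedback, Notch pathway, and Wnt pathway targets and ligands. Each was tested against the other genes of its table with cameraPR of limma 3.58.1 on the signed normal quantile of the authors' p-value, with an inter-gene correlation of 0.01, two-sided, and Benjamini-Hochberg adjustment over the lists of a comparison. Values per sample are needed to estimate the correlation, so 0.05 was used as the alternative, with a rank-based form beside it. A list with only 1 measured member was not tested, which concerned the erythroid list where measured and, in the PKH-negative Myc-ER table, the milk proteins. Counts of changed members are given over all genes and adjusted over the list alone.

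Pairs of comparisons were compared by the genes called in both, with the overlap of independent lists per direction. For pairs that share libraries, 100 draws of unchanged groups were simulated with the spread that the implied errors give per gene, the shared libraries entering both comparisons. For Nutlin-3 with ErbB2 the spread was that of the ErbB2 table alone, with no pairing by tumour. The difference between the 2 Myc-ER comparisons was tested per gene as the difference of fold changes over its combined error (normal approximation, Benjamini-Hochberg) and per list with cameraPR.

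Alternatives were an adjusted p below 0.01, an added minimum absolute log2 fold change of 1, genes with a mean at or above the table's median, a recomputed adjustment, the higher correlation and the rank form of the list test, and for pairs a minimum fold change or all genes by sign. The log2 ratio of means for named genes, its difference between the Myc-ER comparisons and the pair of Nutlin-3 with the knockout were added after the data were seen. On simulated data the p53 list, shifted by 1 unit over the 13873 genes of the Myc-ER table, was recovered in 100% of 20 draws and 0.179% of unshifted lists were called. The simulated values were independent between genes and had the spread of unchanged genes, whereas 50.8% of the real genes were called. These rates therefore need not hold for the real list tests. The test of the difference between the Myc-ER comparisons recovered 87.5% of genes that differed by 2 on the log2 scale, over 13431 genes, and 5.41% of its calls were false. The simulated fold changes were not reduced below the ratio of means as the authors' are, so 5.41% need not hold for the real calls. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.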

Results

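Gene expression was measured by RNA sequencing in mouse mammospheres, the floating spheres that mammary cells form in non-adherent culture. The 24 libraries fell into 8 groups of mice on the FVB background. Wild-type mammospheres carried an empty lentiviral vector (3 libraries) or a lentivirus for Myc-ER (3 libraries), a fusion of Myc to the hormone-binding part of the oestrogen receptor, and were taken at passage 3. Mammospheres from ErbB2-driven breast tumours were left untreated (5 libraries) or given Nutlin-3 (3 libraries), a compound that blocks the binding of Mdm2 to p53, at 2.5 µM for 72 h. Trp53-knockout mammospheres (2 libraries) were, like the tumour ones, not infected and were taken at passages 6 to 7. Wild-type cells stained with PKH, a membrane dye that is diluted at each division and so stays in cells that have divided little, were sorted at passage 1 into PKH-high (2 libraries) and PKH-negative cells (3 libraries). PKH-negative cells were also studied with the Myc-ER lentivirus at passage 3 (3 libraries). No ligand for the fusion is named in the labels of the Myc-ER samples. The authors' mean normalised counts, summed over the listed genes, lay between 36651122 and 48054435 per group and table.

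Every gene-level mean, log2 fold change and adjusted p-value below is that of the authors' deposited table for the comparison named. The value after ± is the standard error that the authors' p-value implies for their fold change. A gene is said to rise or fall where the authors' adjusted p was below 0.05. Better expressed genes are those with a mean at or above the median of the changed genes of a table, and the largest increases and decreases are named among these. Gene lists were tested against the other genes of the same table, and list p-values were adjusted over the lists of a comparison.

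**Figure D1:**
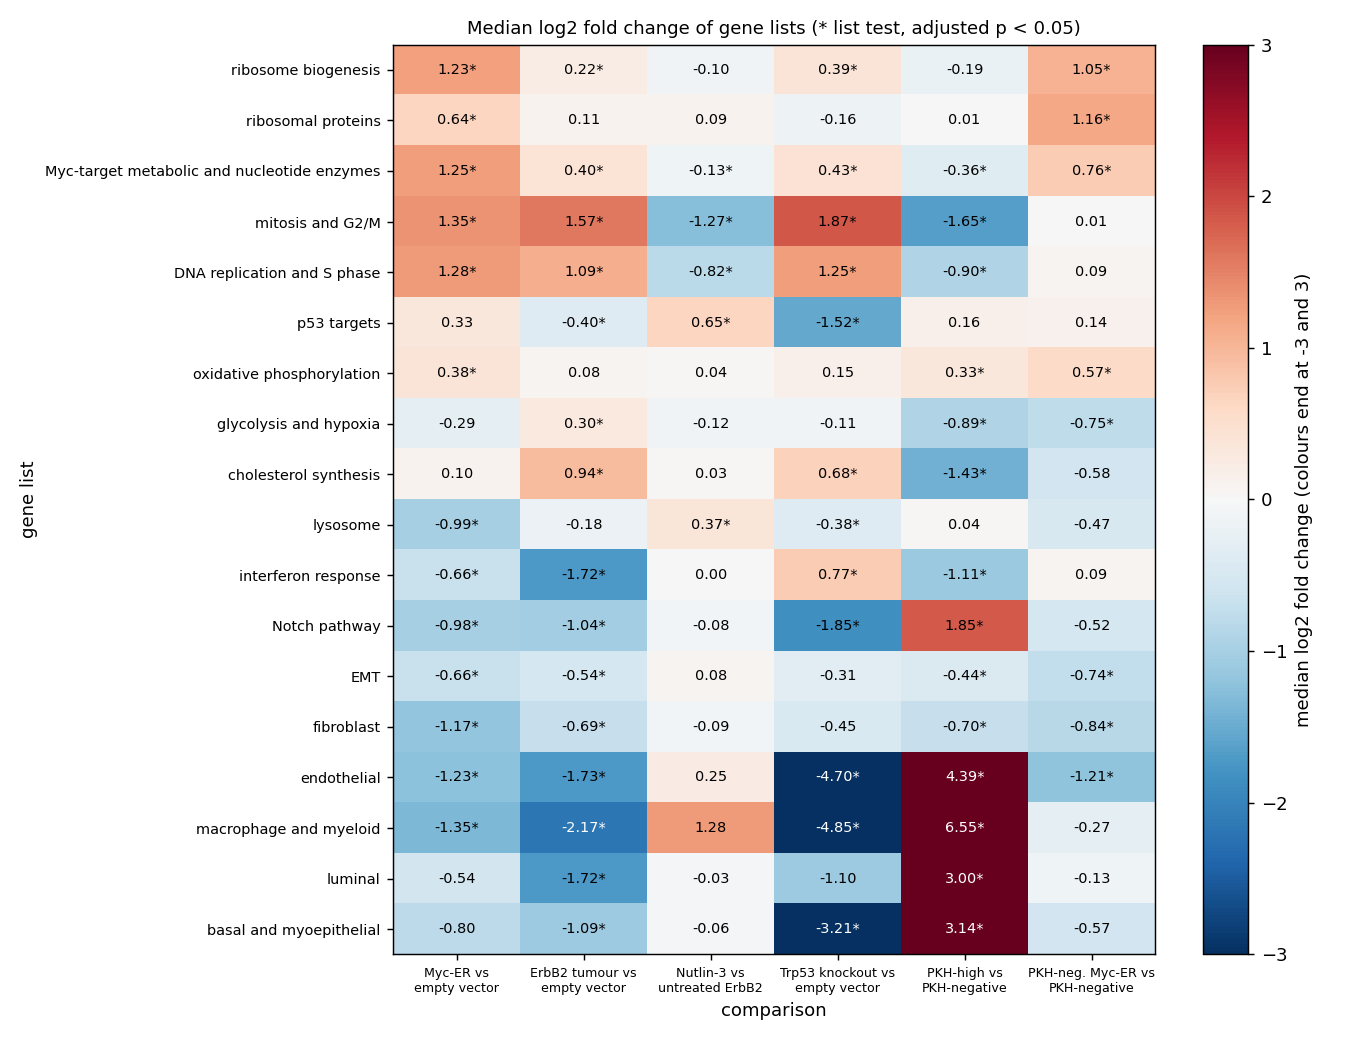
Median log2 fold change of 18 gene lists (vertical axis) in the 6 comparisons (horizontal axis), from the authors' deposited tables. Colour and number give the median and an asterisk marks a list test with an adjusted p below 0.05. The mitosis list has medians of 1.35, 1.57 and 1.87 in the comparisons with the empty vector, -1.27 with Nutlin-3 and -1.65 in PKH-high cells.

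Myc-ER against the empty vector asked what the fusion changes in wild-type mammospheres. Genes for making ribosomes rose as a group: all 35 measured members of the ribosome biogenesis list were higher, among them the RNA polymerase I subunit Polr1b (2.15 ± 0.12), the rRNA pseudouridine synthase Dkc1 (2.08 ± 0.22) and nucleolin, Ncl (1.63 ± 0.16). Enzymes of one-carbon and nucleotide metabolism rose with them, including Shmt1 (2.45 ± 0.31), Mthfd1 (2.30 ± 0.17) and the pyrimidine synthesis enzyme Cad (2.18 ± 0.13). Of 42 mitosis genes 40 rose, with the checkpoint kinase gene Bub1b at 2.14 ± 0.42 and the anaphase activator Cdc20 at 1.77 ± 0.36. Genes with large decreases included the collagen gene Col15a1, which went from a mean of 28841 to 3185 normalised counts (-3.16 ± 0.11), with the microfibril gene Mfap5 at -2.68 ± 0.13 and Igf1 at -2.56 ± 0.29. Of 13873 genes listed there, 7052 changed by the adjusted p of the authors' deposited table, 3703 upward and 3349 downward.

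The fusion itself was visible in 2 genes of the authors' deposited table. Myc had a mean of 16782 normalised counts against 2975 with the empty vector (2.45 ± 0.20, adjusted p = 2.75e-31), and Esr1, whose reads include those of the receptor part of the fusion, 152198 against 129. The table cannot tell reads of the fusion from those of the cell's own Myc or Esr1 gene. Trp53 rose (0.85 ± 0.09) and so did the p53 target Mdm2 (1.24 ± 0.25), whereas Cdkn1a (0.15 ± 0.16, adjusted p = 0.42) and Erbb2 (-0.31 ± 0.16, adjusted p = 0.0821) did not pass. Other large increases were those of the carbonic anhydrase gene Car12 (2.86 ± 0.41) and the folate carrier gene Slc19a1 (2.61 ± 0.13), and other large decreases those of the calcium sensor gene Hpca (-2.82 ± 0.42) and the prostaglandin transporter gene Slco2a1 (-2.46 ± 0.42).

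By list, the median log2 fold change was 1.23 for ribosome biogenesis (adjusted p = 6.28e-46; 35 higher adjusted over the list alone) and 1.25 for Myc-target metabolic and nucleotide enzymes, of which 23 of 24 rose (adjusted p = 1.74e-17; 23 adjusted over the list alone). The mitosis list had a median of 1.35 (adjusted p = 3.41e-05; 41 higher adjusted over the list alone). For DNA replication and S phase 35 of 38 members rose, with Cdc6 at 1.77 ± 0.37 and the ribonucleotide reductase subunit Rrm2 at 1.64 ± 0.31 (adjusted p = 5.13e-06; 36 adjusted over the list alone). All 35 ribosomal protein genes rose, by a median of 0.64, with Rpl3 at 0.88 ± 0.20 (adjusted p = 3.21e-07; 35 adjusted over the list alone). Oxidative phosphorylation followed, where 24 of 32 genes of oxidative phosphorylation rose while 1 fell (adjusted p = 2.63e-04; 28 and 1 adjusted over the list alone). Lysosome genes fell in 15 of 17 cases, with cathepsin D, Ctsd, at -1.21 ± 0.21 (adjusted p = 1.24e-08; 16 adjusted over the list alone). In the fibroblast list 11 of 19 members fell and 2 rose, with periostin, Postn, at -2.05 ± 0.10 and Fbln2 at -1.79 ± 0.34 (adjusted p = 5.60e-05; 13 and 2 adjusted over the list alone). The list of epithelial-mesenchymal transition (EMT) genes had 14 of 20 lower and 2 higher (adjusted p = 1.45e-04; 14 and 2 adjusted over the list alone).

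Markers of other cell types moved with the fusion as well. Of 16 macrophage and myeloid markers 13 fell, with C1qc at -2.10 ± 0.70 (13 adjusted over the list alone; list adjusted p = 0.0148), and of 16 endothelial markers 10 fell (11 adjusted over the list alone; list adjusted p = 0.029). Interferon response genes fell in 15 of 27 cases, with Irf7 at -1.58 ± 0.33 (15 adjusted over the list alone; list adjusted p = 0.0217). Notch pathway genes fell in 7 of 13, with Hey1 at -2.29 ± 0.45 (7 adjusted over the list alone; list adjusted p = 0.0254). With an inter-gene correlation of 0.05 these last 4 list calls were lost, with an adjusted p = 0.0693 for macrophage, adjusted p = 0.11 for endothelial, adjusted p = 0.117 for interferon and adjusted p = 0.0873 for Notch. In the rank-based form of the test these lists had an adjusted p = 3.70e-04, 0.00121, 7.06e-04 and 0.0131. Of 30 p53 targets 15 rose, among them Bbc3 at 1.33 ± 0.15, and 2 fell (17 and 2 adjusted over the list alone), and the list test did not pass (adjusted p = 0.058), though it did in the rank-based form (adjusted p = 0.019).

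ErbB2-tumour mammospheres against empty-vector wild-type ones asked what distinguishes tumour-derived spheres. All 42 mitosis genes were higher in the tumour spheres, with the kinetochore gene Cenpf at 2.33 ± 0.32 and the spindle gene Aspm at 2.25 ± 0.32, and 35 of 38 genes of DNA replication and S phase, with cyclin E2, Ccne2, at 1.77 ± 0.40. Cholesterol synthesis genes rose in 20 of 25 cases, including the thiolase gene Acat2 (1.45 ± 0.34) and the isomerase gene Idi1 (1.38 ± 0.32). Interferon response genes fell in 23 of 28 cases, Oas2 by the most among those named (-5.82 ± 0.57), followed by the nucleic acid sensor gene Zbp1 (-4.97 ± 0.53). The authors' deposited table called 3596 of 13288 genes changed, 1791 upward and 1805 downward.

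Myc itself did not pass in this comparison (0.33 ± 0.21, adjusted p = 0.258), nor did Trp53 (0.30 ± 0.13, adjusted p = 0.0651). In the authors' deposited table Cdkn1a (-0.78 ± 0.27) and Mdm2 (-0.69 ± 0.19) fell. Erbb2 had a mean of 736 normalised counts in the tumour spheres against 1498 (adjusted p = 0.0271), and the table cannot tell whether reads of the transgene are counted under this symbol. The largest named increases of better expressed genes were those of the Wnt modulator gene Dkk2 (6.14 ± 0.73), E-selectin, Sele (5.17 ± 0.45), Vstm2a (4.18 ± 0.34), butyrylcholinesterase, Bche (3.97 ± 0.61), periplakin, Ppl (3.79 ± 0.37), and Tinagl1 (3.79 ± 0.63). Among better expressed genes the largest decreases included tenascin C, Tnc (-5.44 ± 0.50), the homeobox gene Alx4 (-5.30 ± 0.49), the metalloproteinase inhibitor gene Timp1 (-5.08 ± 0.53) and Tnfrsf26 (-5.81 ± 0.69).

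Among the lists, mitosis had a median of 1.57 (adjusted p = 8.87e-27; 42 higher adjusted over the list alone), DNA replication 1.09 (adjusted p = 3.97e-15; 36 adjusted over the list alone) and cholesterol synthesis 0.94 (adjusted p = 3.06e-07; 20 adjusted over the list alone). Fatty acid synthesis genes rose in 7 of 12 cases, with the acetyl-CoA synthetase gene Acss2 at 2.05 ± 0.49 and Fasn at 1.22 ± 0.28 (adjusted p = 0.0021; 8 adjusted over the list alone). Ribosome biogenesis had 8 of 35 members higher, with Rrs1 at 0.78 ± 0.08 (adjusted p = 0.00274; 8 adjusted over the list alone). The Myc-target enzymes had 10 of 24 higher, with ornithine decarboxylase, Odc1, at 2.05 ± 0.52 (adjusted p = 0.00144; 11 higher and 1 lower adjusted over the list alone). Of 30 p53 targets 10 fell, with Sfn at -2.85 ± 0.65, Pmaip1 at -2.59 ± 0.73 and Perp at -2.57 ± 0.71, and 1 rose (adjusted p = 0.00429; 10 and 1 adjusted over the list alone). The interferon list had a median of -1.72 (adjusted p = 8.19e-15; 25 lower adjusted over the list alone). Immediate early genes fell in 8 of 16 cases, with Atf3 at -3.09 ± 0.71 and Fos at -2.29 ± 0.79 (adjusted p = 0.00274; 8 adjusted over the list alone). Notch pathway genes fell in 4 of 12 cases and rose in 1, with Hey1 at -5.87 ± 0.74 (adjusted p = 0.0078; 4 and 1 adjusted over the list alone).

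Markers of cell lineages were lower in the tumour spheres, among those listed. Fewer were listed there than for the knockout, with 8 against 16 endothelial, 11 against 20 luminal and 10 against 16 macrophage markers. Macrophage and myeloid markers fell in 7 of 10 cases, with Tyrobp at -6.65 ± 0.92 (adjusted p = 2.87e-06; 8 adjusted over the list alone). Fibroblast markers fell in 7 of 20, with Postn at -4.68 ± 0.60, while 1 rose (adjusted p = 0.0046; 7 and 1 adjusted over the list alone). Luminal markers fell in 4 of 11 cases, with the alveolar regulator Elf5 at -7.26 ± 1.05 and Kit at -4.92 ± 0.47 (adjusted p = 0.00328; 6 adjusted over the list alone). Basal markers fell in 2 of 8 (adjusted p = 0.0148; 2 adjusted over the list alone), a call that the rank-based form of the test lost (adjusted p = 0.113). The calls of 6 further lists were lost with an inter-gene correlation of 0.05. Of these, endothelial markers had 5 of 8 lower and 1 higher, with Sox17 at -7.43 ± 1.01 (5 and 1 adjusted over the list alone; adjusted p = 0.0249, adjusted p = 0.0557 at the higher correlation and adjusted p = 0.0271 in the rank-based form). Mammary stem cell associated genes had 7 of 15 lower and 2 higher, with Axin2 at -4.07 ± 0.42 (7 and 2 adjusted over the list alone; adjusted p = 0.0197, then adjusted p = 0.062 and adjusted p = 0.128). Wnt targets and ligands had 3 of 8 lower (3 adjusted over the list alone; adjusted p = 0.0288, then adjusted p = 0.062 and adjusted p = 0.121). EMT genes had 6 of 20 lower and 2 higher (6 and 2 adjusted over the list alone; adjusted p = 0.0306, then adjusted p = 0.109 and adjusted p = 0.0833). The list of stress response genes, integrated and unfolded protein response together, had 8 of 16 higher and 2 lower, with Chac1 at 1.35 ± 0.45 (9 and 2 adjusted over the list alone; adjusted p = 0.0282, then adjusted p = 0.0863 and adjusted p = 0.0214). Glycolysis and hypoxia had 5 of 23 higher and 1 lower, with Egln3 at 2.81 ± 0.35 (5 and 1 adjusted over the list alone; adjusted p = 0.047, then adjusted p = 0.155 and adjusted p = 0.0878). Age, passage and lentiviral infection differed between the groups along with the tumour, so their effects were not separated from it.

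Nutlin-3 against no treatment in ErbB2-tumour mammospheres asked what stabilised p53 changes in the tumour cells. Of 30 p53 targets 24 rose and none fell, with the membrane protein gene Perp at 2.52, Rprm at 1.82, the death receptor gene Fas at 1.31 and Mdm2 at 1.27. All 42 mitosis genes fell, among them Aspm (-1.49), Mki67 (-1.40), the kinesin gene Kif11 (-1.38) and Cenpf (-1.34), and 36 of 38 genes of DNA replication, with cyclin A2, Ccna2, at -1.41. Lysosome genes rose in 13 of 17 cases, with Ctsd at 0.89. Changed genes numbered 1922 of 13038 in the authors' deposited table, 1005 upward and 917 downward. These fold changes are the authors' means over paired samples and carry no standard error here, because the header defines them apart from the tested coefficient.

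In the authors' deposited table Cdkn1a rose from a mean of 11731 to 21435 normalised counts (0.89, adjusted p = 2.42e-19) and Mdm2 from 10486 to 25473 (adjusted p = 1.75e-29). Myc (-0.17, adjusted p = 0.23), Trp53 (-0.12, adjusted p = 0.344) and Erbb2 (0.10, adjusted p = 0.701) did not pass. Other increases among the largest of better expressed genes were those of Prl2c3 (2.54), a gene of the proliferin family whose near-identical copies can share reads, of the receptor ligand gene Gas6 (1.65), the cholesterol exporter gene Abca1 (1.58), apolipoprotein E, Apoe (1.24), and the glutamate receptor gene Gria3 (1.11).

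The p53 list had a median of 0.65 (adjusted p = 7.35e-31; 24 higher adjusted over the list alone), the mitosis list -1.27 (adjusted p = 3.55e-185; 42 lower adjusted over the list alone), DNA replication -0.82 (adjusted p = 2.14e-66; 37 adjusted over the list alone) and lysosome 0.37 (adjusted p = 5.56e-13; 15 adjusted over the list alone). Genes of the integrated stress and unfolded protein response fell in 10 of 18 cases and rose in 1, with Chac1 at -0.68 and the amino acid transporter gene Slc7a5 at -0.67 (adjusted p = 4.74e-08; 11 and 1 adjusted over the list alone). The Myc-target enzymes had 6 of 24 lower and 1 higher, with Shmt2 at -0.79 (adjusted p = 0.00195; 6 and 1 adjusted over the list alone). Ribosome biogenesis did not pass (2 of 35 lower, median -0.10, adjusted p = 0.0573, and adjusted p = 0.00172 in the rank-based form; 2 adjusted over the list alone). No list call of this comparison was lost with an inter-gene correlation of 0.05. In the macrophage list, 1 of 12 markers passed, upward, with a list median of 1.28 (adjusted p = 0.139; 1 adjusted over the list alone). The macrophage list passed in the rank-based form (adjusted p = 0.0149) and not at the higher correlation (adjusted p = 0.287).

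**Figure D2:**
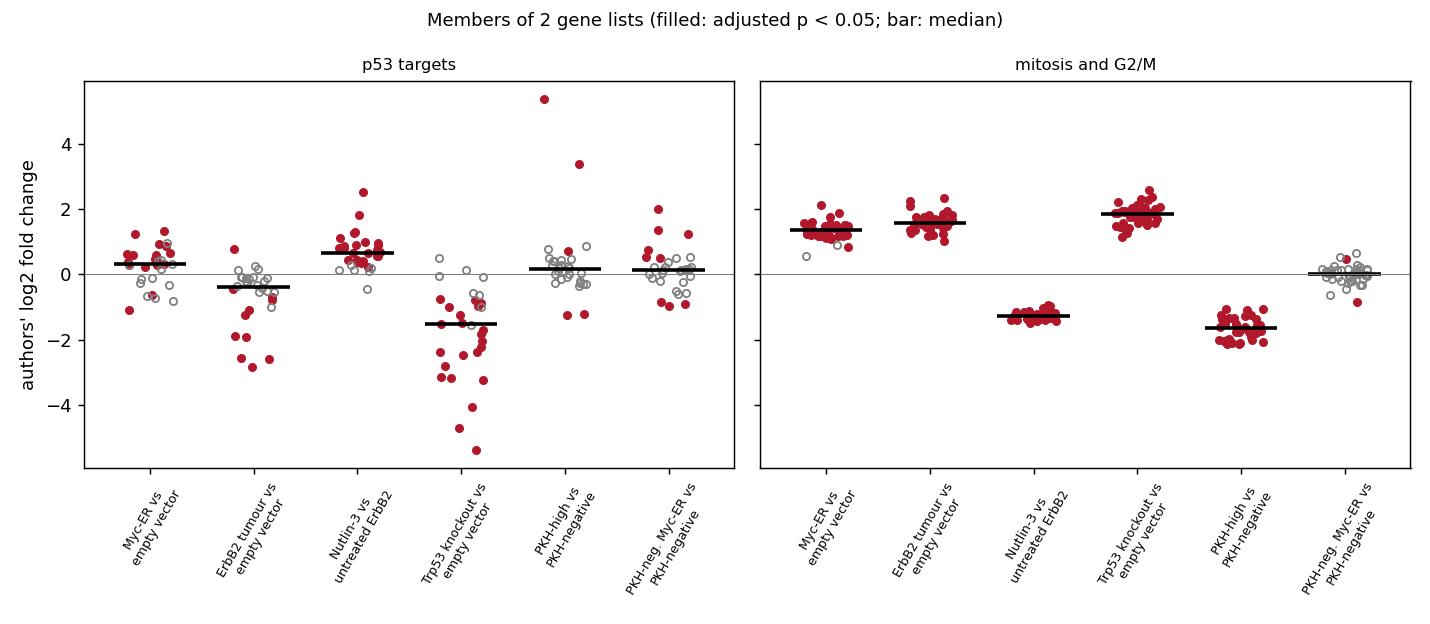
Log2 fold change in the authors' deposited tables (vertical axis) of each measured member of the p53 target list (left) and of the mitosis list (right) in the 6 comparisons (horizontal axis). Filled points passed an adjusted p below 0.05, open points did not, and bars are list medians. The p53 list has medians of 0.65 with Nutlin-3 and -1.52 in the Trp53 knockout.

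Trp53-knockout against empty-vector wild-type mammospheres asked what changes without p53. Of 30 p53 targets 22 fell and none rose, with the death receptor gene Eda2r at -5.39 ± 0.26, Perp at -4.70 ± 0.75, Pmaip1 at -4.07 ± 0.37, Cdkn1a at -3.22 ± 0.24 and Mdm2 at -2.48 ± 0.23. All 42 mitosis genes rose, with Bub1b at 2.60 ± 0.46, and all 38 genes of DNA replication and S phase, with Mcm10 at 2.20 ± 0.40. Markers of macrophages and of endothelium fell strongly, with the lysozyme gene Lyz2 at -7.03 ± 0.48 and the endothelial gene Emcn at -8.18 ± 0.79. Of 14699 genes listed there, 6745 changed by the adjusted p of the authors' deposited table, 3279 upward and 3466 downward.

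The targeted gene was still counted in the knockout group. Trp53 had a mean of 2998 normalised counts against 4207 in the authors' deposited table (-0.49 ± 0.12, adjusted p = 2.40e-04), and the sources used here do not say which part of the gene was removed. On GRCm38, Trp53 lies on chromosome 11, 69580359.0 to 69591873.0, Cdkn1a on chromosome 17, 29090976.0 to 29100727.0, Mdm2 on chromosome 10, 117688875.0 to 117710758.0, Myc on chromosome 15, 61985391.0 to 61990374.0 and Erbb2 on chromosome 11, 98412470.0 to 98437716.0. Myc was higher in the knockout (0.75 ± 0.11, adjusted p = 1.90e-10) and Erbb2 lower (-1.56 ± 0.33). The largest named increases of better expressed genes were those of Trim30d (7.63 ± 0.32), whose family has close copies, of Dkk2 (5.51 ± 0.46), Fam5c (5.29 ± 0.48), haptoglobin, Hp (5.14 ± 0.23), and Slc22a23 (5.12 ± 0.21). Among better expressed genes the largest decreases were those of the interferon-inducible gene Ifi202b (-9.03 ± 0.37), which also has close copies, the chemokine gene Cxcl14 (-8.55 ± 0.80), Gpr133 (-8.41 ± 0.53), the mast cell tryptase gene Tpsab1 (-7.90 ± 0.81), Ptprv (-7.74 ± 0.39) and Alx4 (-7.65 ± 0.42).

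The p53 list had a median of -1.52 (adjusted p = 5.87e-20; 22 lower adjusted over the list alone), the mitosis list 1.87 (adjusted p = 8.57e-11; 42 higher adjusted over the list alone) and DNA replication 1.25 (adjusted p = 3.20e-08; 38 adjusted over the list alone). Ribosome biogenesis genes rose in 19 of 35 cases, with Dkc1 at 1.30 ± 0.23 (adjusted p = 1.03e-04; 19 adjusted over the list alone). Myc-target enzymes rose in 11 of 24, with Shmt1 at 1.67 ± 0.35 (adjusted p = 0.00278; 13 higher and 1 lower adjusted over the list alone). Cholesterol synthesis rose in 19 of 25 members (adjusted p = 7.37e-06; 20 adjusted over the list alone) and fatty acid synthesis in 8 of 12, with 1 lower (adjusted p = 0.00231; 9 and 1 adjusted over the list alone). Interferon response genes rose in 13 of 28 cases, with Xaf1 at 2.20 ± 0.34 and Gbp3 at 1.72 ± 0.51 (adjusted p = 0.00231; 13 adjusted over the list alone). Notch pathway genes fell in 11 of 13 cases, with Heyl at -7.44 ± 0.81 (adjusted p = 1.50e-05; 11 adjusted over the list alone). Immediate early genes fell in 12 of 16 (adjusted p = 0.004; 13 adjusted over the list alone) and lysosome genes in 8 of 17, with Ctsd at -1.46 ± 0.13 (adjusted p = 0.00478; 8 adjusted over the list alone).

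Macrophage and myeloid markers fell in 15 of 16 cases in the knockout, with a median of -4.85 (adjusted p = 3.22e-09; 15 adjusted over the list alone). Endothelial markers fell in 13 of 16 cases and rose in 1, with a median of -4.70 and the receptor gene Tie1 at -7.83 ± 0.76 (adjusted p = 3.22e-09; 14 and 1 adjusted over the list alone). Basal and myoepithelial markers fell in 7 of 11 cases, with keratin 14, Krt14, going from a mean of 246 to 1.02 normalised counts (adjusted p = 0.00606; 7 lower and 1 higher adjusted over the list alone). Luminal markers had 9 of 20 lower and 3 higher, with Epcam at -5.30 ± 0.90, and the list test did not pass (adjusted p = 0.251; 9 and 4 adjusted over the list alone). No list call of this comparison was lost with an inter-gene correlation of 0.05. Passage and lentiviral infection differed between these groups along with the genotype.

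PKH-high against PKH-negative cells asked what distinguishes the cells of wild-type mammospheres that kept the dye from those that had lost it. All 42 mitosis genes were lower in PKH-high cells, with the kinesin gene Kif20a at -2.14 ± 0.42 and cyclin B1, Ccnb1, at -2.11 ± 0.34, as were 21 of 38 genes of DNA replication. All 25 measured cholesterol synthesis genes were lower too, with the lanosterol synthase gene Lss at -2.04 ± 0.22, and 20 of 23 genes of glycolysis and hypoxia. Markers of several lineages were far higher in PKH-high cells: keratin 5, Krt5 (6.54 ± 0.63), keratin 8, Krt8 (6.04 ± 0.40), the macrophage gene C1qc (8.41 ± 0.81) and the endothelial regulator Sox17 (5.58 ± 0.66). The authors' deposited table called 4285 of 13959 genes changed, 2176 upward and 2109 downward.

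Myc was lower in PKH-high cells (-0.49 ± 0.19, adjusted p = 0.0416) and so was Trp53 (-0.61 ± 0.13, adjusted p = 1.67e-05) in the authors' deposited table. Erbb2 (-0.31 ± 0.19, adjusted p = 0.209), Cdkn1a (0.29 ± 0.20, adjusted p = 0.27) and Mdm2 (-0.13 ± 0.30, adjusted p = 0.797) did not pass. The largest named increases of better expressed genes were all of genes of myeloid cells or their secreted products, namely C1qc, the lysozyme genes Lyz1 (8.30 ± 0.47) and Lyz2 (8.15 ± 0.47), which are close copies, Wfdc17 (8.17 ± 0.39), cathepsin S, Ctss (7.80 ± 0.44), and the chemokine gene Ccl6 (7.38 ± 0.73). The largest named decreases of such genes were those of the basophil protease gene Mcpt8 (-3.53 ± 0.18), Sele (-3.31 ± 0.37), Thbs4 (-3.06 ± 0.38), Unc13a (-2.97 ± 0.22), stanniocalcin, Stc1 (-2.70 ± 0.22), and Serpina3f (-2.69 ± 0.16), a gene of a family with close copies.

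Cell-type lists moved by different amounts. Macrophage and myeloid markers were higher in 16 of 17 cases, with a median of 6.55 (adjusted p = 2.40e-46; 17 adjusted over the list alone). Endothelial markers were higher in 12 of 16, with 1 lower and a median of 4.39 (adjusted p = 6.18e-06; 14 and 1 adjusted over the list alone). Luminal markers rose in 18 of 24 cases and fell in 1, and keratin 18, Krt18, had a mean of 10199 normalised counts against 123 (adjusted p = 5.65e-22; 19 and 1 adjusted over the list alone). Basal markers rose in 11 of 15 cases and fell in 1, with Krt14 at a mean of 1746 against 25.1 (adjusted p = 9.96e-09; 11 and 1 adjusted over the list alone). Lymphocyte markers rose in 4 of 5 cases, with the leukocyte gene Ptprc at 5.24 ± 0.51 (adjusted p = 3.26e-04; 4 adjusted over the list alone). Fibroblast markers, by contrast, fell in 10 of 20 and rose in 1 (adjusted p = 0.00159; 12 and 1 adjusted over the list alone). Mammary stem cell associated genes rose in 5 of 16 cases and fell in 1, with a list median of 0.27 and Sox10 at 5.61 ± 0.43 (adjusted p = 0.00426; 5 and 1 adjusted over the list alone). The rank-based form lost that call (adjusted p = 0.104). Notch pathway genes rose in 9 of 13 and fell in 1, with Nrarp at 4.97 ± 0.72 (adjusted p = 0.00231; 11 and 1 adjusted over the list alone).

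**Figure D3:**
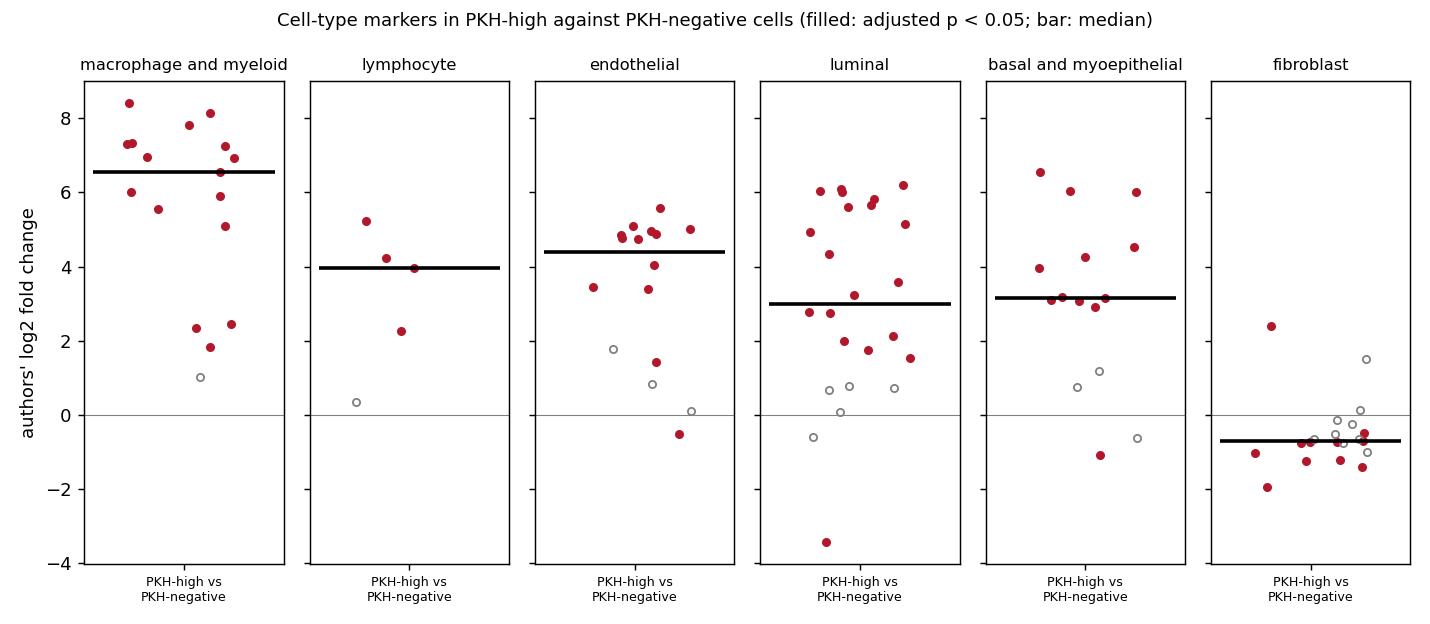
Log2 fold change in the authors' deposited table (vertical axis) of each measured marker of 6 cell types in PKH-high against PKH-negative cells, with 1 panel per list. Filled points passed an adjusted p below 0.05, open points did not, and bars are medians. The medians are 6.55 for macrophage, 3.96 for lymphocyte, 4.39 for endothelial, 3.14 for basal and -0.70 for fibroblast markers.

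The mitosis list had a median of -1.65 in PKH-high cells (adjusted p = 5.48e-16; 42 lower adjusted over the list alone), DNA replication -0.90 (adjusted p = 2.57e-05; 22 adjusted over the list alone) and cholesterol synthesis -1.43 (adjusted p = 1.12e-22; 25 adjusted over the list alone). Glycolysis and hypoxia had 1 member higher beside those lower (adjusted p = 1.41e-13; 20 lower and 2 higher adjusted over the list alone). Fatty acid synthesis fell in 10 of 13 members and rose in 1 (adjusted p = 9.41e-09; 10 and 1 adjusted over the list alone). The Myc-target enzymes fell in 11 of 24, with Shmt1 at -1.37 ± 0.17 (adjusted p = 0.00119; 11 adjusted over the list alone). Interferon response genes fell in 21 of 28, with Ifi44 at -2.30 ± 0.40 (adjusted p = 3.46e-08; 22 lower and 1 higher adjusted over the list alone). Genes of the integrated stress and unfolded protein response fell in 9 of 18 cases and rose in 2, with Psat1 at -1.32 ± 0.19 (adjusted p = 0.00769; 10 and 2 adjusted over the list alone). BCL2 family genes rose in 5 of 13 cases, with Bik at 5.36 ± 0.51 and Bmf at 3.80 ± 0.72, both known to promote cell death (adjusted p = 0.0129; 5 adjusted over the list alone). The basement membrane list had 5 of 15 members higher and 3 lower, with Lama5 at 5.16 ± 0.46; its median was -0.06 while its test pointed upward, a call lost in the rank-based form (adjusted p = 0.0086, then adjusted p = 0.563; 6 and 3 adjusted over the list alone). With an inter-gene correlation of 0.05, 3 calls were lost. These were EMT (7 of 20 lower, 1 higher, 8 and 1 adjusted over the list alone; adjusted p = 0.0153, then adjusted p = 0.0663, and adjusted p = 0.00417 by ranks), oxidative phosphorylation (10 of 32 higher, 10 adjusted over the list alone; adjusted p = 0.0154, then adjusted p = 0.0965, and adjusted p = 2.99e-04 by ranks) and adipocyte markers (5 of 9 higher, 6 adjusted over the list alone; adjusted p = 0.0254, then adjusted p = 0.0597, and adjusted p = 0.00624 by ranks). The labels name the dye as the only criterion of the sort.

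Myc-ER in PKH-negative cells against uninfected PKH-negative cells asked what the fusion changes in the cells that had lost the dye. All 35 ribosome biogenesis genes rose, with Ncl at 1.63 ± 0.17, nucleophosmin, Npm1, at 1.49 ± 0.25 and Dkc1 at 1.47 ± 0.12. All 35 ribosomal protein genes rose as well, with Rps14 at 1.82 ± 0.50 and Rps27a at 1.68 ± 0.49. Of 42 mitosis genes 1 passed upward and 1 downward, with a median of 0.01. Inflammatory genes fell in 10 of 18 cases, including the chemokine gene Cxcl5 (-2.83 ± 0.59) and the acute-phase gene Saa3 (-2.42 ± 0.48), and genes of glycolysis and hypoxia in 15 of 23, with adrenomedullin, Adm, at -3.44 ± 0.49 and Bnip3 at -1.80 ± 0.21. Changed genes numbered 5388 of 14382 in the authors' deposited table, 2722 upward and 2666 downward.

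Myc had a mean of 28517 normalised counts with the fusion against 5996 without (2.03 ± 0.39, adjusted p = 2.36e-06), and Esr1 256081 against 80, in the authors' deposited table. Mdm2 rose (0.51 ± 0.17, adjusted p = 0.00768) and Erbb2 fell (-0.41 ± 0.17, adjusted p = 0.0362), whereas Trp53 (0.15 ± 0.16, adjusted p = 0.499) and Cdkn1a (-0.12 ± 0.13, adjusted p = 0.486) did not pass. Other large increases were those of Car12 (3.46 ± 0.27), the glutathione transferase gene Gsta4 (3.17 ± 0.19), the phosphatase gene Dusp9 (3.02 ± 0.20), Mex3a (2.82 ± 0.27) and Dlk1 (2.63 ± 0.66). The means of Dlk1, 24799 against 90.4, have a log2 ratio of 8.10, far above the authors' fold change. The largest decreases of better expressed genes were those of Serpina3h (-5.30 ± 0.20), Serpina3i (-5.01 ± 0.22) and Serpina3f (-4.94 ± 0.30), close copies that can share reads, and of Gpr133 (-4.78 ± 0.20), the cytokine signalling inhibitor gene Socs2 (-4.31 ± 0.31) and follistatin, Fst (-4.19 ± 0.36).

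Ribosome biogenesis had a median of 1.05 (adjusted p = 2.08e-25; 35 higher adjusted over the list alone) and ribosomal proteins 1.16 (adjusted p = 3.90e-12; 35 adjusted over the list alone). The Myc-target enzymes rose in 16 of 24 cases and fell in 1, with the chaperonin gene Hspe1 at 1.45 ± 0.38 and spermidine synthase, Srm, at 1.35 ± 0.30 (adjusted p = 2.72e-06; 17 and 1 adjusted over the list alone). Oxidative phosphorylation rose in 21 of 32 (adjusted p = 7.09e-07; 25 adjusted over the list alone). Glycolysis and hypoxia had a median of -0.75 (adjusted p = 8.46e-07; 18 lower adjusted over the list alone) and the inflammatory list -1.32 (adjusted p = 2.13e-04; 12 adjusted over the list alone). EMT genes fell in 12 of 20 cases, with Lox at -2.29 ± 0.25 (adjusted p = 3.15e-04; 12 lower and 1 higher adjusted over the list alone). Fibroblast markers fell in 8 of 20, with Mfap5 at -3.58 ± 0.21 (adjusted p = 9.48e-04; 8 adjusted over the list alone), and endothelial markers in 10 of 15, with Vwf at -2.27 ± 0.42 and Tek at -2.04 ± 0.29, while 1 rose (adjusted p = 0.00491; 10 and 1 adjusted over the list alone). Lymphocyte markers went the other way, with 4 of 8 higher, 0 lower and a median of 1.58 (5 higher adjusted over the list alone). Their median mean was 26.8 normalised counts against 7.03. That list test did not pass (adjusted p = 0.0708), though it did in the rank-based form (adjusted p = 0.00746). Neither mitosis (adjusted p = 0.958) nor DNA replication (2 of 38 higher, adjusted p = 0.502) passed the list test, and adjusted over the list alone 0 and 2 members rose. No list call of this comparison was lost with an inter-gene correlation of 0.05. Passage and infection differed between the groups along with the fusion.

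Changes were then compared between pairs of comparisons. Myc-ER and the ErbB2 tumour moved 1990 of the 2150 genes called in both the same way (92.6%), 1033 upward and 957 downward, where independent lists would share 486 and 442. All 42 mitosis genes rose in the tumour spheres and 40 with Myc-ER, with Bub1b the member that rose most with the fusion (2.14). Myc-ER and the Trp53 knockout moved 3292 of 3761 genes the same way (87.5%), 1630 upward and 1662 downward, against 812 and 813 for independent lists. The p53 targets went against this: of 30, 12 rose with Myc-ER and fell in the knockout, while 1 fell and 0 rose in both. The tumour and the knockout moved 2347 of 2470 genes the same way, 1184 upward and 1163 downward, against 402 and 416, and Dkk2 and Alx4 were among the largest changes of better expressed genes in both. Interferon response genes went against this: of 28, 10 fell in the tumour and rose in the knockout, and 0 were called in the same direction. Of 30 p53 targets 9 fell in both. Over the 13143 genes in all 3 tables, 801 rose and 693 fell in every one, against 110 and 103 for independent lists.

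All 3 comparisons used the empty-vector libraries, which alone make fold changes correlate. For unchanged groups against the same controls the simulated covariance of the fold changes across genes was 0.0718, against 0.445 observed, for Myc-ER and the tumour, 0.0520 against 0.558 for Myc-ER and the knockout, and 0.0808 against 0.961 for the tumour and the knockout. Pearson's r across genes, which are not independent replicates, was 0.510, 0.508 and 0.648 for these pairs, against simulated values of 0.560, 0.446 and 0.499. The share of all genes with the same sign was 69.9%, 70.0% and 73.5%, against 68.9%, 64.7% and 66.7% simulated, so that for Myc-ER and the tumour r and the sign share lay below or close to the value expected with no effect. The controls could not be split, and part of the excess may come from the shared controls.

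Genes that differed between tumour and wild-type spheres and also responded to Nutlin-3 mostly moved the other way with it. Of 869 genes called in both, 810 (93.2%) moved in opposite directions, 556 falling with Nutlin-3 and higher in the tumour and 254 the reverse, where independent lists would give 127 and 111. Mitosis genes, with medians of 1.57 and -1.27, were among them. The tumour libraries enter both comparisons with opposite sign; the covariance was -0.132 against -0.0583 for unchanged groups, and r was -0.374 against -0.338. Of all genes 63.6% had opposite signs, and in the simulated unchanged groups 39.1% had the same sign. The simulated groups were independent while the authors paired the Nutlin-3 samples by tumour, so variation between tumours that cancels within pairs makes these simulated values too negative. How much of the opposite movement arises with no effect therefore cannot be told from them. The pair of Nutlin-3 and the Trp53 knockout, which shares no libraries and was chosen after the data were seen, had 1151 of 1265 genes (91.0%) in opposite directions, with r = -0.360 across genes. Of these 549 rose with Nutlin-3 and fell in the knockout, where independent lists would give 216, with the p53 targets Cdkn1a (0.89 and -3.22) and Perp (2.52 and -4.70) among them.

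Myc-ER in PKH-negative cells shared fewer changes with the PKH-high state. Of 1539 genes called in both, 1104 (71.7%) moved the same way, 369 upward and 735 downward, against 331 and 404 for independent lists. The covariance was 0.147 against 0.0449 for unchanged groups with the same PKH-negative libraries, while r was 0.181 against 0.445 and 58.0% of all genes had the same sign against 64.7% simulated. Part of the excess may come from the shared controls. Glycolysis and hypoxia genes fell in both (-0.89 and -0.75), whereas ribosome biogenesis had medians of -0.19 and 1.05.

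The 2 Myc-ER comparisons share no libraries. They called 3473 genes in common, of which 3380 (97.3%) moved the same way, 1841 upward and 1539 downward, against 703 and 607 for independent lists, with r = 0.623 across genes. Ncl rose by 1.63 in unsorted and 1.63 in PKH-negative cells. The fold changes differed for 859 of 13431 genes by a normal test of the difference over its combined standard error, 341 with a higher value in PKH-negative cells and 518 with a lower one. Mitosis genes differed as a list, with a median difference of -1.38 (PKH-negative less unsorted, adjusted p = 1.27e-12), while 2 of 42 members differed by themselves. DNA replication did so too (-1.09, adjusted p = 1.66e-13), with 11 of 38 members differing by themselves. Neither difference was lost with an inter-gene correlation of 0.05, and the uninfected controls of the PKH-negative cells were at passage 1 while all other groups here were at passage 3.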

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

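Of the tests of explanations in this part, the one on the level of the fusion was chosen only after the result was seen, as was the difference by the ratio of means. The difference between the 2 Myc-ER comparisons was planned, and what follows lists the results for which that difference passed its test (PKH-negative less unsorted response, adjusted p below 0.05). Passage and infection differ between the PKH-negative groups and not between the unsorted ones, so these differences cover both the cells and the culture history.

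Cell-cycle genes responded less in PKH-negative cells as lists, with a median difference of -1.38 for mitosis and -1.09 for DNA replication. By themselves 2 of 42 and 11 of 38 members differed, including Rrm2 (-2.06 ± 0.56) and Cdc6 (-1.78 ± 0.58). Ribosome biogenesis (-0.22) and the Myc-target enzymes (-0.54) had lower responses there too, with Shmt1 at -1.62 ± 0.45 and Mthfd1 at -1.21 ± 0.39, whereas ribosomal proteins (0.53) and oxidative phosphorylation (0.25, adjusted p = 0.0637 with an inter-gene correlation of 0.05 and 7.40e-04 by ranks) had higher ones. The inflammatory list (-0.85), with Cxcl5 at -3.85 ± 0.84, and glycolysis and hypoxia (-0.60), with Adm at -1.68 ± 0.56, had lower responses in PKH-negative cells. Their medians were -1.32 and -0.75 there, against -0.12 and -0.29 in unsorted cells. In unsorted cells neither passed the list test (adjusted p = 0.583 and adjusted p = 0.18), and the inflammatory list had 4 members higher and 4 lower. Cxcl5 had a log2 fold change of 1.02 in unsorted and -2.83 in PKH-negative cells. Cholesterol synthesis (-0.59, adjusted p = 0.0749 with the higher correlation and 6.75e-04 by ranks) had medians of -0.58 in PKH-negative and 0.10 in unsorted cells. The lysosome (0.50) and macrophage lists (1.07, adjusted p = 0.0749 with the higher correlation and 0.0109 by ranks) fell less in PKH-negative cells. Their medians were -0.47 and -0.27, against -0.99 and -1.24. Interferon genes (0.63) had medians of 0.07 and -0.66, with Mx1 at 4.29 ± 0.49 the only 1 of 27 that differed by itself. The lymphocyte list (1.79, 4 measured) had medians of 1.15 and -0.79. By themselves, 0 of 35 ribosomal protein, 0 of 17 lysosome and 0 of 10 macrophage genes differed.

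Among other named genes the difference was 4.03 ± 0.77 for Esr1, -0.71 ± 0.18 for Trp53, 2.21 ± 0.60 for Col15a1, 2.05 ± 0.41 for Gsta4, 1.17 ± 0.25 for Dusp9 and 1.25 ± 0.38 for Cdkn2a. The size of the Esr1 difference depends on the measure, since by the ratio of means it is 1.44. The authors' Esr1 fold changes lie below that ratio by unequal amounts. Which measure is nearer the true difference cannot be told without values per library. Differences below 0 were -4.09 ± 0.74 for Serpina3h, -3.85 ± 0.69 for Serpina3i and -3.34 ± 0.57 for Serpina3f, and -2.03 ± 0.37 for Gpr133, -2.77 ± 0.39 for Socs2, -1.34 ± 0.40 for Fst, -1.01 ± 0.24 for Cdkn2d and -0.90 ± 0.24 for Mfap5.

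The response of mitosis genes to Myc-ER was weighed further, since ribosome biogenesis genes and the Myc-target enzymes rose in both settings. A weaker expression of the fusion in PKH-negative cells is argued against by the Esr1 mean, which was 1.68 times that in the infected unsorted cells, across tables normalised separately. A high level before infection goes with it. The uninfected PKH-negative mean of the list exceeded the empty-vector wild-type mean by a median of 1.22 on the log2 scale beyond all genes. The upper limit for random lists of like expression was 0.132, and 100% of the 42 members lay above 0. Both control means enter the difference to be explained, so this gap is part of it and not separate support. The median mean of the list was 2058 normalised counts in infected PKH-negative and 2228 in infected unsorted cells. These levels were also compared across separately normalised tables. The uninfected PKH-negative cells were at passage 1 and the empty-vector cells at passage 3, so passage, the sort and the virus stay open as the reason for the high level.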

How the results depend on the processing

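The alternative counting of named genes by the log2 ratio of means and the pair of Nutlin-3 with the Trp53 knockout were chosen after the data were seen; the others were set before the data were examined. No paired analysis was possible because the tables hold only group means, and the Nutlin-3 table was already paired by the authors. For the same reason leaving out each replicate, a replicate block, other splits of the samples, the search for samples far from their group, another count tool, another pseudocount and quantile scaling were not run. Depth limits the tables through the minimum mean of 10, below which genes are not listed, and through group sizes of 2 to 5 libraries. That minimum is not the only reason for a missing gene. Of the 183 genes nearly absent from the knockout, all with a control mean of at least 100, some were not listed for the tumour. The reason was not tested. An adjusted p below 0.01 and a recomputed adjustment left all 6 counts of changed genes within 1.5 times of the main ones.

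With a minimum absolute log2 fold change of 1, changed genes numbered 2237 for Myc-ER, 2062 for ErbB2, 260 for Nutlin-3, 3428 for the knockout, 2263 for PKH-high and 2353 for Myc-ER in PKH-negative cells. Among genes with a mean at or above the table's median, with no new adjustment, they numbered 4130, 1566, 1277, 3271, 1936 and 2806 in the same order. The main counts were 7052, 3596, 1922, 6745, 4285 and 5388. Both settings count fewer genes by construction. They also moved the split by direction: 26.5% of the 260 Nutlin-3 genes were higher, against 52.3% of all called, and 38.2% of the 2062 ErbB2 genes, against 49.8%. For PKH-high the settings moved it in opposite directions, to 62.7% of 2263 genes with the minimum fold change and to 28.5% of 1936 at or above the median mean, against 50.8%.

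The rank-based list test called 11 lists with Nutlin-3, against 6, and 15 with Myc-ER in PKH-negative cells, against 9; the cause was not tested. Over all comparisons it added 15 list calls and lost 7, namely the basal, mammary stem cell, EMT, glycolysis and Wnt lists in the tumour spheres and the mammary stem cell and basement membrane lists in PKH-high cells. An inter-gene correlation of 0.05 lost 13 and left 178 list results on their side of the threshold, with no direction reversed.

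Counting only genes with an absolute log2 fold change of at least 1 in both, the share moving the same way was 95% for Myc-ER and ErbB2, 91.4% for Myc-ER and the knockout and 96.0% for both Myc-ER comparisons, and the share moving oppositely was 98.4% for Nutlin-3 and ErbB2 and 95.6% for Nutlin-3 and the knockout. Over all genes by sign these shares were 69.9%, 70.0%, 76.0%, 63.6% and 64.2%, with 73.5% for ErbB2 and the knockout and 58.0% for Myc-ER in PKH-negative cells and PKH-high. Genes that pass no test enter there by construction, and for Nutlin-3 and ErbB2 unchanged groups, simulated without the pairing by tumour, gave 39.1% with the same sign.

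Of the named genes, counted once per comparison, 482 kept their side of the threshold at an adjusted p below 0.01 and 48 lost the call. A minimum absolute log2 fold change of 1 lost 98 calls, and a mean at or above the table's median lost 184. The log2 ratio of means differed from the authors' fold change by more than its error, or for Nutlin-3 by more than 20% of it, for 54 and by less for 472, and no called gene changed sign.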

Other observations

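Of the tests in this part, those on the amounts by which lineages moved, on passage and virus, on cell types lost in the knockout, on Nutlin-3 with the knockout and on the PKH-high genes in the other comparisons were chosen only after the result was seen.

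Some members of the ErbB and Wnt lists changed in the authors' deposited tables, although the ErbB list passed in no comparison and the Wnt list only in the tumour spheres (adjusted p = 0.0288), a call lost at the higher inter-gene correlation (adjusted p = 0.062) and by ranks (adjusted p = 0.121). Egfr, a receptor that pairs with ErbB2, was lower with Myc-ER (-1.34 ± 0.20), in ErbB2-tumour spheres (-1.66 ± 0.60), in the knockout (-2.19 ± 0.88) and with Myc-ER in PKH-negative cells (-1.83 ± 0.32), and higher with Nutlin-3 (0.46). Its partner Erbb3 was lower in the tumour spheres (-4.57 ± 0.92) and in the knockout (-3.07 ± 0.66) and higher in PKH-high cells (2.22 ± 0.43). The list of ErbB ligands and MAPK feedback genes had 2 higher and 6 lower of 21 in the knockout (adjusted p = 0.251; 2 and 6 adjusted over the list alone). The Wnt potentiator gene Rspo1 fell with Myc-ER (-3.27 ± 0.54), in the tumour (-4.42 ± 0.80) and in the knockout (-3.09 ± 0.91), while the ligand genes Wnt5b (3.91 ± 0.59) and Wnt7b (3.63 ± 0.70) rose in the knockout, where the Wnt list did not pass (adjusted p = 0.585). Lipocalin 2, Lcn2, rose in the tumour (2.74 ± 1.02) and in the knockout (2.74 ± 0.61).

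Among CDK inhibitors, Cdkn2a rose in the knockout (2.71 ± 0.14) and with Myc-ER in PKH-negative cells (2.25 ± 0.35), Cdkn1b rose in the tumour (1.08 ± 0.26) and in the knockout (1.40 ± 0.31), and Cdkn1c (-1.78 ± 0.58) and Cdkn2b (-1.68 ± 0.42) fell in the tumour. With Myc-ER in PKH-negative cells Cdkn2d (-1.97 ± 0.16) and Cdkn1c (-1.56 ± 0.34) fell. In unsorted cells Myc-ER also raised Cdkn2a (0.997) and lowered Cdkn2d (-0.960), while Cdkn1c was at 0.278 and did not pass. The list passed in no comparison, with 2 higher and 1 lower of 7 in the knockout (adjusted p = 0.263; 2 and 1 adjusted over the list alone), and 1 higher and 3 lower of 7 with Myc-ER in PKH-negative cells (adjusted p = 0.204; 1 and 3 adjusted over the list alone). In PKH-high cells 2 of 4 measured milk protein genes were higher and 1 lower, with Btn1a1 at 4.48 ± 0.63 (adjusted p = 0.418; 2 and 1 adjusted over the list alone). Squamous differentiation genes had 4 of 9 higher and 2 lower there, with Krt6a at 3.74 ± 0.64 (adjusted p = 0.404; 4 and 2 adjusted over the list alone). Of the erythroid list 1 member was measured in the Myc-ER table, with a log2 fold change of -1.28 that did not pass over all genes.

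The macrophage, lymphocyte, endothelial, luminal and basal lists passed upward in PKH-high cells, although 1 endothelial, 1 luminal and 1 basal marker fell. The fibroblast list passed downward, with a median mean of 16845 normalised counts in PKH-high and 27240 in PKH-negative cells. In PKH-negative cells the luminal and basal lists had median means of only 66.3 and 71.7. Which cell types made up the PKH-negative cells was not tested. Cells of other types in the sort are a possible explanation. Of a second leukocyte list, written before its values were seen and holding none of the fixed list genes, 94.7% of the 19 measured genes were called higher. Their median mean was 353 normalised counts against 11.6. The macrophage and lymphocyte lists were already higher in the same libraries, so this second list is not separate support. Lyz2 had a mean of 27635 against 73.8, and the epithelial Krt8 12333 against 162; the labels name only the dye as a criterion of the sort. The lists moved by different amounts (permutation p = 0.0049). A lower share of a single main cell type would raise them alike only if that type expressed none of their markers. That was not tested, so the different amounts do not decide on it. Whether these cells keep the dye in the spheres or come with the fresh tissue at passage 1 was not tested.

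In the knockout 183 genes with a mean of at least 100 in the controls had a mean below 10, and 25 the reverse. Of 284 genes within 10 Mb of Trp53, 17.3% changed at least 2-fold, against 23.5% of 13497 others (Fisher's exact p = 0.995, one-sided). This test counted all such changes and not the genes nearly absent from 1 group, whose positions were not tested. It therefore does not decide on a strain haplotype around Trp53 that alters few genes. A haplotype elsewhere, as for Ifi202b, stays open too. Passage or the lack of lentivirus, shared with the tumour group, stays open: over the 124 of these genes listed for the tumour its median change was 0.618 of the knockout's, but the genes were chosen on controls that both comparisons share, so that value does not decide. A loss of the cell types found in the PKH-high sort may contribute: 53.9% of the 178 such genes listed in that table were higher in PKH-high cells, against 14.0% of the others. The genotype itself stays open beside them.

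The same loss of cells may bear on the tumour comparison with the empty vector. Of 611 genes called at least 8-fold higher in PKH-high cells, 463 were listed with Myc-ER (median log2 fold change -0.81, 99 called lower and 3 higher), 316 in the tumour (-2.57, 201 and 2) and 452 in the knockout (-2.66, 296 and 16). The unlisted genes have no value there. Those called lower were 63.6% in the tumour and 65.5% in the knockout, against 12.4% and 22.3% of the other genes, but 21.4% with Myc-ER against 24.2% of the others, so that for Myc-ER only the median and the low share called higher (0.648% against 27.6%) point the same way. A candidate explanation is that such cells were fewer in the tumour and knockout cultures, while for Myc-ER it stays open, and an effect of Myc or p53 on these genes within the same cells was not tested.

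Outside the p53 list 527 genes rose with Nutlin-3 and fell in the knockout, where independent lists over the 12862 genes would give 210, a ratio of 2.51. These comparisons share no libraries. The ratio only restates the opposite movement with the listed targets taken out, so it does not decide between responses to p53 activity and changes that follow from the opposite movement of cell division.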
